A study of Homo sapiens with 9 samples.

How the data were processed

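Gene expression was measured with Affymetrix human gene arrays in T47D cells, an established human breast cancer line that carries progesterone receptor. The cells used here carried a vector from which doxycycline induces a short hairpin RNA against ELF5. The 9 arrays fell into 3 groups of 3 by their titles: ethanol vehicle; 10 nM ORG2058 for 4 days; and 10 nM ORG2058 with 0.1 µg/ml doxycycline for 4 days. ORG2058 is a synthetic progestin, which the labels call progesterone. The labels give no time in culture for the vehicle arrays and no culture or array batch. A difference in time or batch that coincides with a group can therefore not be told apart from the treatment. The design text describes independent experiments for each condition, and the p-values measure the spread between these arrays.

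The values used were deposited by the authors, 1 per probe set and array, on a log2 scale. The submitters' processing notes name Affymetrix Power Tools, PLIER, Affymetrix Expression Console and limma, with no role, order or version, so which step each tool performed is not given in the sources used here. The background correction and the normalization between arrays are not given there either. That the scale is log2 was read from the values: they reached about 14 on every array, and the lowest was the same on all 9 arrays and was held throughout by 1 probe set without a gene name. PLIER can return values very close to 0 on the linear scale, which become strongly negative on the log2 scale. Among the probe sets with a gene name, 97 values lay below 0 in progestin replicate 3 and 14 to 41 in each other array. Values that low carry no reliable order, and large changes that involve them are given below also on a scale where 16 was added to the linear value before taking log2. That scale was chosen after seeing the data. Median values of the named probe sets lay between 7.19 and 7.28 on the 9 arrays.

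The table held 33297 probe sets. The platform annotation used here gave 1 gene symbol to 19460 of them, several symbols to 1754 and none to 12083. The 21214 probe sets with at least 1 symbol were tested, and genes are named only from probe sets with 1 symbol. Of these, 19429 were matched by gene identifier to a RefSeq gene table of the assembly GRCh38.p14, which changed 0 symbols. That table was used only for names, because the array files name no genome build, and no coordinates are given. The 18417 distinct single symbols included 769 genes with more than 1 probe set. For such a gene, the probe set with the highest mean over all 9 arrays stood for it in the gene lists. Genes whose probe sets carry several symbols are not counted in the lists.

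Each comparison was tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 arrays, moderated variances (eBayes) and Benjamini-Hochberg adjustment over the 21214 probe sets, at an adjusted p of 0.05. All adjusted p values of single genes come from this model unless another setting is named, and SE is the standard error of the log2 change in it. The residual standard deviation had a median of 0.151, and the standard error of a change a median of 0.12. The number of arrays limits the precision, and with 3 arrays against 3 an exact permutation test cannot give a p under 0.1. Gene lists were tested with camera, two-sided, with a preset correlation of 0.01 between genes, and adjusted over the 22 lists of a comparison. The same test with an estimated correlation, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. The 22 lists were written from general knowledge and were not chosen on these samples; they hold 566 gene entries, of which 513 were measured by a probe set with a single symbol. They cover progestin-induced genes, estrogen receptor and luminal genes, basal and myoepithelial genes, alveolar and milk genes, replication, mitosis, CDK inhibitors and pocket proteins, p53 targets, interferon response, ETS factors, EGFR family and ERK feedback, Wnt and Notch targets, steroid metabolism, cholesterol synthesis, fatty acid synthesis and storage, hypoxia and glycolysis, the unfolded protein response, the ATF4 integrated stress response, the cytosolic ribosome, mitochondrial ribosome and respiration, integrins, laminins and adhesion, and markers of stromal, endothelial and immune cells.

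The named genes follow a rule. ELF5 and PGR are always given. For progestin against vehicle, and for progestin plus doxycycline against progestin, the rule takes the 10 highest and 10 lowest changes among single-symbol probe sets past the threshold whose 2 groups of arrays do not overlap. It also takes up to 4 members of each list with the smallest p values among those past the threshold, or the 2 smallest where none passed. Of the genes called in both comparisons with opposite signs, it takes the 10 with the largest changes. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data.

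The procedure was tested on simulated data with the real group sizes, in which 200 of the 21214 probe sets were changed. For progestin against vehicle, 29.6% of changes of 0.5 on the log2 scale were recovered, 80.7% of changes of 1 and 93.5% of changes of 2, with 9 of 21014 unchanged probe sets called. For progestin plus doxycycline against progestin the shares were 25.4%, 77.6% and 90.9%, with 8 unchanged probe sets called. The alternatives were quantile normalization, median centring, leaving out the dimmest 25% of probe sets, testing every row of the table, a replicate block, a variance trend with robust estimation, array weights, fitting only the groups compared, other thresholds, testing all 3 groups together by an F test before the pairs, and leaving out each array in turn. The closing section gives their effects. With the F test first, p values were adjusted for the joint test and not for each pair, so its counts stand at another threshold. Comparisons that share arrays share chance values, so 100 simulated data sets without any effect gave the correlations and overlaps that arise when no group differs. The series had no arm with doxycycline and without this hairpin among the arrays used here, so effects of the hairpin and of doxycycline itself cannot be told apart.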

Results

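The arrays measured RNA levels in T47D breast cancer cells given vehicle, the progestin ORG2058, or ORG2058 with doxycycline to induce the hairpin against ELF5, with 3 arrays in each group. ELF5 is a transcription factor of the ETS family that directs the alveolar lineage of the mammary gland. The design asks how much of the transcriptional response to progestin passes through ELF5. Rank correlations of all named probe sets were 0.989 to 0.995 between arrays of a group (9 pairs), 0.949 to 0.962 between vehicle and progestin-treated arrays (18 pairs), and 0.986 to 0.993 between arrays with progestin alone and with doxycycline added (9 pairs).

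ELF5 is the target of the hairpin, and its level checks the labels. It (probe set 7947481) was at 10.17 ± 0.109 with vehicle, 11.28 ± 0.0455 with progestin and 10.42 ± 0.0608 with progestin plus doxycycline (log2, mean ± SD, n = 3 arrays each). Progestin raised it 2.16-fold (log2 change 1.11, SE 0.08, adjusted p = 2.06e-05), and adding doxycycline lowered it 1.82-fold (log2 change -0.87, SE 0.08, adjusted p = 0.029). In the cells with doxycycline 21.8% of the log2 rise remained (0.24, SE 0.08, adjusted p = 0.0502). Over the alternatives this adjusted p lay between 0.00319 and 0.137, and it was under 0.05 with quantile normalization (0.0109), without the dimmest 25% of probe sets (0.0322), with a variance trend and robust estimation (0.00319), with array weights (0.0267) and with 16 added to the linear values (0.0475). The groups did not overlap in any of the 3 comparisons, and the exact permutation test gave its smallest possible p of 0.1 for each. The drop with doxycycline lay between -0.89 and -0.83 with any 1 array left out. Its adjusted p then lay between 0.0263 and 0.149, and stayed under 0.05 only without vehicle replicate 3. The adjusted p of the drop was 0.175 when only the 2 groups were fitted and 4.25e-08 with a variance trend and robust estimation.

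**Figure D1:**
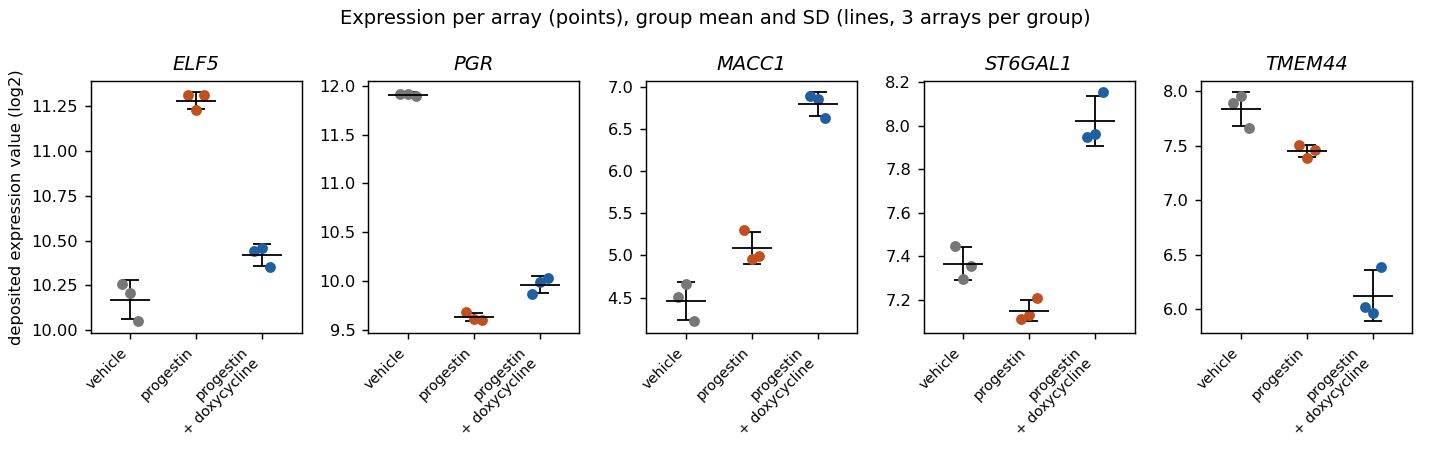
Deposited expression values (log2, vertical axis, a separate scale for each gene) of ELF5, PGR, MACC1, ST6GAL1 and TMEM44 on the 9 arrays, by group; points are arrays, and lines give the mean and SD of 3 arrays. ELF5 rose from 10.17 to 11.28 with progestin and lay at 10.42 with doxycycline added, while MACC1 lay at 4.46, 5.08 and 6.79.

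Progestin against vehicle compared cells after 4 days of the hormone with vehicle cells, whose time in culture the labels do not give. Of the interferon response list 30 of 30 measured genes rose, while 31 of 31 mitosis genes and 30 of 33 DNA replication genes fell. The other 3 replication genes were not called, and 2 of the 33 had a positive change. The 3 lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.0801 for interferon response, 0.0789 for mitosis and 0.0801 for replication with an estimated correlation). Progestin-induced genes that rose included SGK1, a kinase (log2 change 4.39, SE 0.08), and HSD11B2, which inactivates cortisol (3.65, SE 0.12). The mRNA of the progesterone receptor itself, PGR, fell 4.84-fold, from 11.91 ± 0.021 to 9.63 ± 0.0445 (log2, SD, n = 3; adjusted p = 2.96e-07). In all, 6161 of 21214 probe sets changed (29.0%), 2848 higher and 3313 lower, and 1129 of them by at least 2-fold, 547 higher and 582 lower. The 2 groups of arrays did not overlap for 42.3% of probe sets, against 10% by chance.

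The 10 highest changes on the scale as deposited included those of genes with almost no signal in vehicle, whose size and order are not reliable on that scale. MYBPC1, which encodes a myosin-binding protein, went from -2.90 ± 4.86 to 7.68 ± 0.129, and SGPP2, a sphingosine-1-phosphate phosphatase, from -1.12 ± 5.54 to 9.01 ± 0.115 (log2, SD, n = 3). With 16 added to the linear values their changes were 3.73 and 4.74. On that scale CDSN, the corneodesmosome protein corneodesmosin, rose by 3.35 to 3.44 on its 3 probe sets, UGT2B10, which conjugates drugs with glucuronic acid, by 2.56, and ATP13A4, a cation-transporting ATPase, by 2.90. The UGT2B10 call was lost on the scale as deposited without any of 7 arrays (adjusted p up to 0.105): vehicle replicate 1 and every array of the other 2 groups. TRIM22, an interferon-induced antiviral protein, rose by 6.60 (SE 0.13), and KCNMA1, a calcium-activated potassium channel, by 6.37 (SE 0.25). The small nucleolar RNA SNORD115-4 was among the 10 highest at 9.21, but both groups had mean values below 0, and its change was 0.21 on the scale with 16 added, with an adjusted p of 0.257.

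The 10 lowest changes included those of SLITRK6, a neuronal membrane protein (-4.68, SE 0.12), GFRA1, the receptor for the growth factor GDNF (-3.84, SE 0.08), HEY2, a Notch target (-3.60, SE 0.08), and the chemokine CXCL12 (-3.52, SE 0.09). ANKRD7 (-5.05), CDC20B (-3.99), DNAJC5B (-3.72), TGFBR3, a TGF-beta co-receptor (-3.70), and NCAM2, a neural adhesion molecule (-3.37), fell as well. HP, the plasma protein haptoglobin, had the lowest change of all, -8.55, from progestin values of -6.19 ± 6.09. On the scale with 16 added it was -0.37, and its call on the scale as deposited was lost with any array but progestin replicate 2 left out (adjusted p up to 0.103).

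The interferon response list had a median log2 change of 3.67. IFI44 rose by 5.85, IFIT1, which binds viral RNA, by 5.29 and IFIT3 by 4.87 (SE 0.11 each). Camera gave an adjusted p of 7.45e-33, and the adjusted p = 0.0801 with an estimated correlation. Of 21 progestin-induced genes 17 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 1.25; beside SGK1 and HSD11B2 they included S100P, a calcium-binding protein (5.65), and STAT5A, the signal transducer of prolactin (4.07). Camera gave an adjusted p of 1.26e-14 for this list (adjusted p = 0.0789 with an estimated correlation). ELF5 is itself one of its members.

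The mitosis list had a median of -1.55. Log2 changes were -1.91 for HMMR, -1.80 for the spindle checkpoint kinase BUB1B and -1.73 for TOP2A, which untangles chromosomes (SE 0.07 each; camera adjusted p = 2.97e-30; adjusted p = 0.0789 with an estimated correlation). The replication list had a median of -1.15, and 0 of its genes rose. The helicase subunit MCM2 was at -1.39 and the origin licensing factor CDT1 at -1.58 (camera adjusted p = 1.05e-21; adjusted p = 0.0801 with an estimated correlation). Of 9 CDK inhibitors and pocket proteins 2 rose and 3 fell (3 and 3 adjusted over the list alone): CDKN1B, the inhibitor p27, rose by 0.51, while RBL1, a relative of the retinoblastoma protein (-0.80), and CDKN2A (-0.54) fell (camera adjusted p = 0.731; median 0.03, mean -0.06). Of 16 p53 targets 2 rose and 3 fell, with the secreted factor GDF15 at 1.87 and the repair protein DDB2 at -0.64 (camera adjusted p = 0.578; the median, -0.16, and the mean, 0.03, differ in sign).

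Alveolar and milk genes rose in 9 of 22 cases and fell in 1, with a median of 0.30 (camera adjusted p = 0.00431; adjusted p = 0.0801 with an estimated correlation). They included SLPI, a protease inhibitor of secretions (4.44), STAT5A, STAT5B (1.41) and the mucin MUC1 (0.71). Among 28 steroid metabolism genes 10 rose and 3 fell (12 and 3 adjusted over the list alone), with HSD11B2, the steroid reductase SRD5A1 (1.32) and HSD17B1 (1.08) higher and the estrogen-hydroxylating CYP1B1 lower (-1.46). The camera adjusted p of this list was 0.0217, and adjusted p = 0.0923 with an estimated correlation. The call was also lost with quantile normalization (adjusted p = 0.06) and without the dimmest 25% of probe sets (adjusted p = 0.249).

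Of 18 cholesterol synthesis genes 1 rose and 9 fell (1 and 13 adjusted over the list alone), with a median of -0.30. INSIG1, which holds back sterol synthesis, was at -1.41, and the enzymes EBP, HMGCS1 and SQLE at -0.79, -0.71 and -0.69 (camera adjusted p = 0.000204; adjusted p = 0.459 with an estimated correlation). Fatty acid synthesis and storage genes went both ways, 9 of 24 higher and 4 lower, with ACSL1 (2.72), which activates fatty acids, and fatty acid synthase FASN (2.21) among those that rose (camera adjusted p = 0.278). Hypoxia and glycolysis genes rose in 6 and fell in 13 of 25 cases; the glycolytic genes ALDOC (-0.91), GPI (-0.86) and ENO2 (-0.85) fell, and the glucose transporter SLC2A1 rose (0.65). The camera adjusted p of that list was 0.0228, adjusted p = 0.504 with an estimated correlation, 0.184 with quantile normalization and 0.0565 without the dimmest 25% of probe sets.

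Cytosolic ribosome genes fell in 16 of 25 cases and rose in 0 (18 and 0 adjusted over the list alone), with a median of -0.27 and RPS2 at -0.49 (camera adjusted p = 1.66e-06; adjusted p = 0.458 with an estimated correlation). Mitochondrial ribosome and respiration genes fell in 7 of 25 cases and rose in 0 (8 and 0 adjusted over the list alone), with a median of -0.15. TFAM, which maintains mitochondrial DNA, was at -0.68 (camera adjusted p = 0.0217 for the list; adjusted p = 0.742 with an estimated correlation). That list was not called without vehicle replicate 2 (adjusted p = 0.0988) or progestin replicate 2 (0.0714), nor with quantile normalization (0.118) or without the dimmest 25% of probe sets (0.0565).

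Estrogen receptor and luminal genes rose in 6 and fell in 11 of 22 cases (8 and 11 adjusted over the list alone), with PGR, CXCL12, the transcription factor MYB (-1.25) and IGFBP5 (-1.08) lower. The camera adjusted p of the list was 0.0785, and 0.0465 without progestin replicate 3. Integrin, laminin and adhesion genes rose in 6 and fell in 14 of 32 cases, with fibronectin FN1 at -1.42, ITGB6 at -1.76 and the tight junction protein CLDN1 at 1.60. The camera adjusted p of that list was 0.0785, 0.0297 without vehicle replicate 3 and 0.0344 without progestin replicate 3. Among 25 ETS factors 8 rose and 4 fell, with ELF3 (2.67) and EHF (1.30), close relatives of ELF5, among those that rose (camera adjusted p = 0.317; median -0.05, mean 0.19). Members of the EGFR family and ERK feedback list rose in 7 and fell in 5 of 27 cases (8 and 6 adjusted over the list alone), with the feedback inhibitor ERRFI1 at 1.88 and the receptors EGFR and ERBB2 both at 1.26 (camera adjusted p = 0.516).

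Wnt and Notch targets rose in 6 and fell in 8 of 26 cases (7 and 8 adjusted over the list alone), with HES1 at 1.34 and NRARP at -1.30 (camera adjusted p = 0.731; median 0.04, mean -0.08). Genes of the ATF4 integrated stress response rose in 6 and fell in 7 of 22 cases (7 and 8 adjusted over the list alone), with DDIT4 at 1.49 and the serine synthesis enzyme PHGDH at -1.41 (camera adjusted p = 0.731). Unfolded protein response genes rose in 6 and fell in 2 of 19 cases (6 and 3 adjusted over the list alone), with HERPUD1 at 0.56 and DNAJB9 at 0.52 (camera adjusted p = 0.144, and 0.0171 with quantile normalization). Basal and myoepithelial genes rose in 4 and fell in 1 of 13 cases, with the smooth muscle protein CNN1 at 0.54 (camera adjusted p = 0.658; median -0.03, mean 0.13). Of 20 markers of stromal, endothelial and immune cells 2 rose and 1 fell; COL1A1, the collagen of fibroblasts, was at -0.42 (adjusted p = 0.0136, and 0.0532 without vehicle replicate 1) and the list had a camera adjusted p of 0.578 (median 0.10, mean -0.15). For lists with no second count, the counts adjusted over the list alone were the same. With an estimated correlation 0 of the 22 lists were called for progestin against vehicle, against 10 with the preset one and 15 with fry. Correlation between genes was not the only source of this loss. The estimated correlation was 0.565 for interferon response, 0.336 for mitosis and 0.351 for replication genes, above the preset 0.01. But it was -0.0008 for alveolar and -0.0103 for steroid metabolism genes, below the preset value. Their camera p still rose, from 0.00137 to 0.0125 and from 0.00855 to 0.0252.

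**Figure D2:**
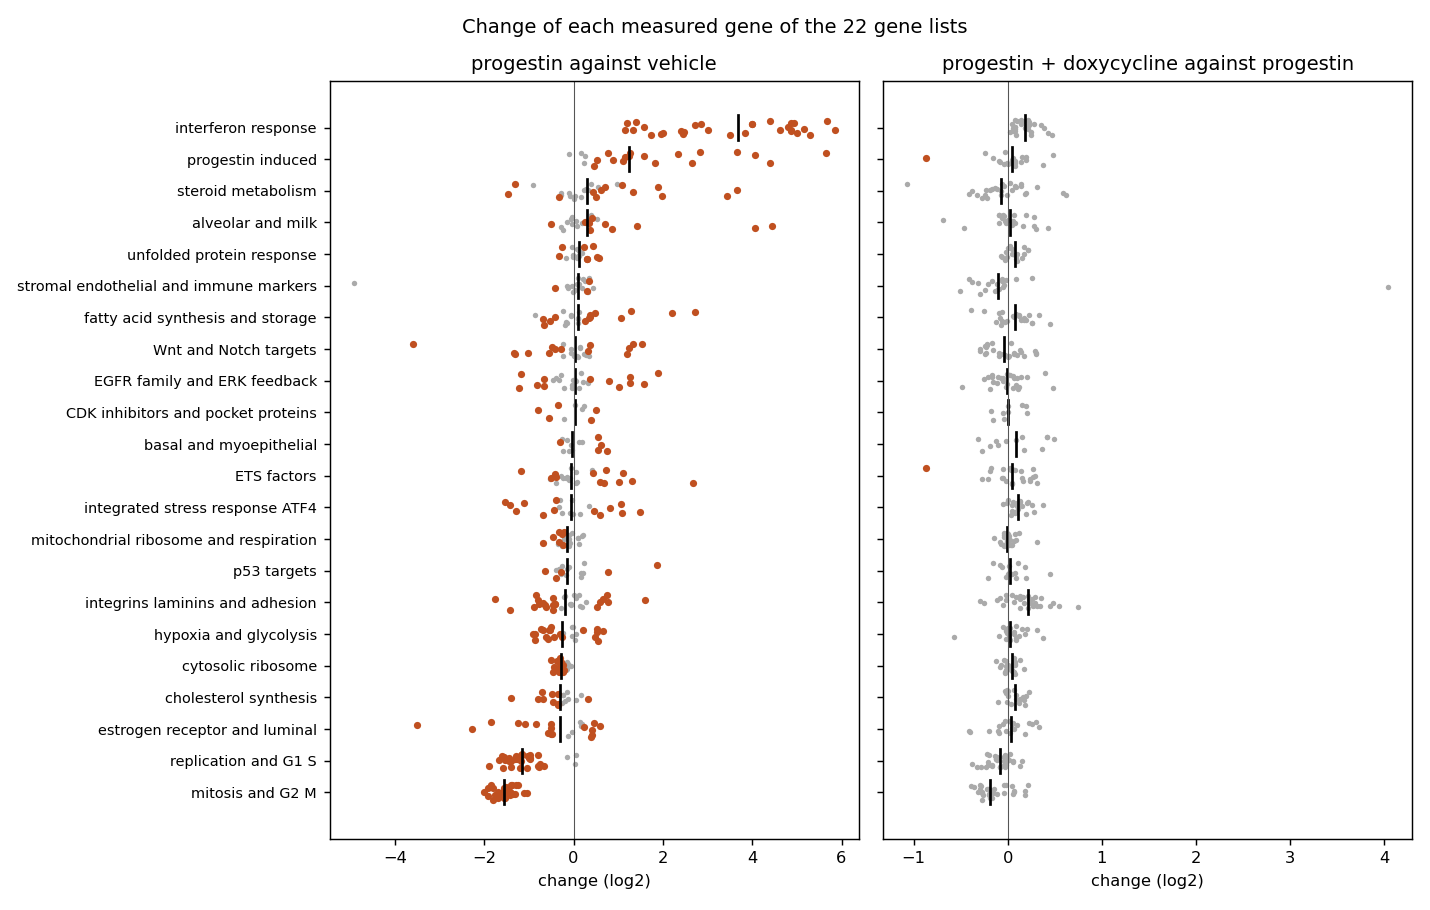
Log2 change (horizontal axes, a separate scale for each panel) of each measured gene of the 22 gene lists, for progestin against vehicle and for progestin plus doxycycline against progestin; points are genes, coloured orange when past an adjusted p of 0.05 over all probe sets tested and grey otherwise, and black bars are list medians. The interferon response list had a median of 3.67 with progestin and 0.19 with doxycycline added, and the mitosis list -1.55 and -0.19.

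Adding doxycycline to progestin asked what follows when the rise of ELF5 is held down. The test called 4 genes. Higher with doxycycline were MACC1, a regulator of MET signalling (probe set level 5.08 ± 0.19 to 6.79 ± 0.139, 3.27-fold), and ST6GAL1, a sialyltransferase of secreted and surface glycoproteins (7.15 ± 0.0493 to 8.02 ± 0.115, 1.83-fold). Lower were TMEM44, a membrane protein (7.45 ± 0.059 to 6.12 ± 0.233, 2.51-fold), and ELF5 (log2, SD, n = 3). Their log2 changes were 1.71, 0.87, -1.33 and -0.87, with SE of 0.14, 0.08, 0.13 and 0.08 and an adjusted p of 0.029 for each. PGR lay at 9.63 ± 0.0445 and 9.96 ± 0.0872 (log2 change 0.33, SE 0.07, adjusted p = 0.132).

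This count depended on the test, on how the variances were modelled and on single arrays. It was 1067 (874 higher, 193 lower) when the 3 groups were tested together by an F test first, 530 (478 higher, 52 lower) with a variance trend and robust estimation, 158 (140 higher, 18 lower) without the dimmest 25% of probe sets, 15 with 16 added to the linear values and 0 when only the 2 groups were fitted. It was 0 without vehicle replicate 1 or 2 or without progestin plus doxycycline replicate 1 or 2, 1 without progestin replicate 2 or 3 or progestin plus doxycycline replicate 3, and 2 without vehicle replicate 3 or progestin replicate 1. An unadjusted p under 0.05 was found for 2969 probe sets, where 1061 were expected by chance, and the 2 groups did not overlap for 21.2% of probe sets, against 10% by chance.

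Of 114 genes with very long mRNAs, listed from general knowledge after the pattern was noticed, 48 had a mean above the median of all genes, and 45 of the 48 (93.8%) had a positive change with doxycycline, with a median log2 change of 0.40. Of the 48 genes 0 passed the test over all genes, and the list had a camera p of 7.06e-30 (p = 0.0385 with an estimated correlation). For all genes above that level the median was 0.05. The 48 genes had a median of -0.05 in progestin against vehicle. The variance trend with robust estimation called 29 of the 48 higher (60.4%), against 2.25% of all probe sets.

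ELF5 was the 1 member of the gene lists that passed the test over all genes with doxycycline added, but 5 lists moved as groups by camera with the preset correlation, and 0 with an estimated correlation or with fry. Integrin, laminin and adhesion genes were higher, with a median of 0.22, 25 of 32 positive and 11 higher adjusted over the list alone; the desmosome protein desmoplakin DSP had a change of 0.75 (SE 0.08, adjusted p = 0.0549) and the laminin chain LAMC1 of 0.48 (SE 0.08, adjusted p = 0.12). The camera adjusted p was 8.89e-06, and adjusted p = 0.977 with an estimated correlation. As a list the long-mRNA genes went the same way as this list and the interferon list, with 45 of 48 changes positive and a median of 0.40. Of the 114 long-mRNA genes listed only 1 is in any gene list, and a link of transcript length with either list was not tested. Interferon response genes had a median of 0.19, with 30 of 30 positive and 0 past the threshold adjusted over the list alone, and IFIT2 at 0.47 (SE 0.12). The camera adjusted p was 0.00071, and adjusted p = 0.986 with an estimated correlation. Mitosis genes were lower, with a median of -0.19 and 8 of 31 lower adjusted over the list alone; the cyclin CCNB1 and the ubiquitin conjugating enzyme UBE2C were both at -0.29 (camera adjusted p = 1.51e-07; adjusted p = 0.977 with an estimated correlation). Replication genes had a median of -0.09 and 0 of 33 past the threshold adjusted over the list alone, with the cyclin CCNE1 at -0.38 and thymidine kinase TK1 at -0.22 (camera adjusted p = 0.000169; adjusted p = 0.977 with an estimated correlation). Markers of stromal, endothelial and immune cells had a median of -0.11 and a mean of 0.06, with 3 of 20 positive and the matrix protein LUM, named after its values were seen, at a progestin mean of -1.66 (camera adjusted p = 0.0158, direction down; adjusted p = 0.977 with an estimated correlation). That last list was not called without progestin replicate 1 (adjusted p = 0.059) or progestin plus doxycycline replicate 2 (0.158), with quantile normalization (0.0743), with the mean of a gene's probe sets (0.0724) or without the dimmest 25% of probe sets (0.12).

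The other 17 lists were not called by camera with doxycycline added. ETS factors and progestin-induced genes each had 1 gene called, ELF5, and median changes of 0.04 and 0.04 (camera adjusted p = 0.966 for both; 1 higher and 1 lower adjusted over the list alone in each). Alveolar and milk genes had a median of 0.02 and a camera adjusted p of 0.966, with SLPI at 0.43 and PRLR, the prolactin receptor, at 0.28. Estrogen receptor and luminal genes had a median of 0.03 and a mean of 0.01, with CXCL12 at -0.41 and a camera adjusted p of 0.966 in the downward direction; 2 were higher and 1 lower adjusted over the list alone. The medians of the EGFR family and ERK feedback, steroid metabolism, and Wnt and Notch lists were -0.01, -0.07 and -0.04 (camera adjusted p = 0.824, 0.554 and 0.81), with EGFR at 0.48, AKR1C3 at 0.62 and NOTCH1 at 0.30. Those of cholesterol synthesis, fatty acid synthesis and storage, and hypoxia and glycolysis were 0.08, 0.08 and 0.02 (0.305, 0.81 and 0.81), with the sterol enzyme SC5D at 0.23, malic enzyme ME1 at -0.39 and the peptide hormone gene ADM at -0.57. Those of the unfolded protein response and the ATF4 integrated stress response were 0.08 and 0.10 (0.305 and 0.159). The latter was called without vehicle replicate 3 (adjusted p = 0.0249) and without progestin plus doxycycline replicate 3 (0.0215). Those of the cytosolic ribosome, mitochondrial ribosome and respiration, p53 targets, basal and myoepithelial genes, and CDK inhibitors were 0.04, -0.01, 0.02, 0.09 and -0.0018 (0.966, 0.81, 0.966, 0.966 and 0.966), and the means of the mitochondrial and CDK inhibitor lists were positive, at 0.01 each. Adjusted over the list alone, PRLR, EGFR and AKR1C3 were each the 1 gene higher in these lists, NOTCH1 and NOTCH3 were the 2 higher Wnt and Notch targets, ME1 was the 1 lower fatty acid gene, and the lists with no such count had 0.

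Progestin plus doxycycline against vehicle asked how much of the hormone response was present with ELF5 held down. Interferon response genes (30 of 30 higher, median 3.75), progestin-induced genes (16 of 21 higher, median 1.34), mitosis genes (31 of 31 lower, median -1.74) and replication genes (31 of 33 lower, median -1.18) changed again. For each of these 4 lists the adjusted p = 0.0772 with an estimated correlation. In all 5953 probe sets changed (28.1%), 3303 higher and 2650 lower. Which direction held more calls depended on the scaling, with 2788 higher and 3246 lower with median centring and 3395 and 3377 with quantile normalization. Of the 6161 probe sets changed by progestin alone, 4728 (76.7%) were also called here in the same direction and 1 in the opposite one. A probe set not called here is not thereby shown to have lost its change: 6055 of the 6161 had the same sign, called or not. The shared vehicle arrays favour this. With changes from different vehicle arrays 97.3% had the same sign, though the calls themselves came from all vehicle arrays. Independent lists of the sizes called would share 443 higher and 414 lower, and simulated data with the shared vehicle arrays and no effect gave 0. Data without effects give few calls in either comparison, so this 0 is not the chance level of the 4728 shared calls. The correlation of the 2 sets of changes across probe sets, which are not independent replicates, was 0.86 against 0.498 in the simulation, and the covariance 0.337 against 0.045, a difference of 0.292. With changes computed from different vehicle arrays, 2 in the first comparison and 1 in the second, the correlation was 0.703 and the covariance 0.304. In the 10607 probe sets with the higher means, these were 0.937 and 0.337. With shared vehicle arrays the correlation there was 0.967, against 0.499 in the simulation. Part of the excess of shared calls over independent lists may come from the shared vehicle arrays. Camera called 9 lists with the preset correlation, 0 with an estimated one and 17 with fry.

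**Figure D3:**
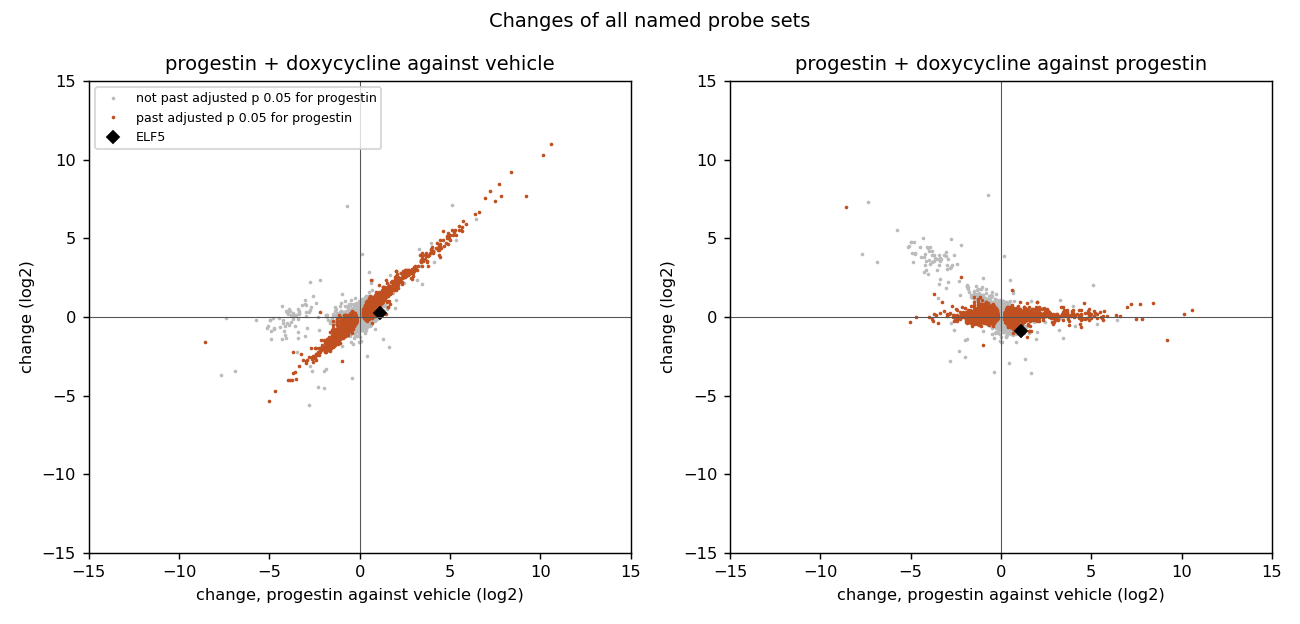
Log2 change with progestin against vehicle (horizontal axes) set against the log2 change with progestin plus doxycycline against vehicle (left) or against progestin (right), for 21214 named probe sets; orange points are past an adjusted p of 0.05 for progestin against vehicle, grey ones are not, and the diamond is ELF5. Changes on the left lie along a rising line with a correlation of 0.86; the grey group at the upper left of the right panel holds probe sets with very low values on single progestin arrays.

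The question of the design was addressed by genes that progestin moved and doxycycline moved back. ELF5, the target of the hairpin, was the 1 gene called in both comparisons with opposite signs. Its call checks the hairpin and does not measure how much of the response passes through ELF5. No other gene was called so. With 1 array left out, ELF5 was so called in 1 of 9 fits, the one without vehicle replicate 3. Without progestin replicate 1, 2 or 3 the 1 gene moved back was another, named after its values were seen: the microRNA gene MIR302B, HP and GABRR3, respectively. The remaining progestin arrays had means of -9.30, -9.71 and 0.17 for these genes, values too low to give a size of change. With 16 added their changes were -0.25, -0.42 and -0.71 with progestin and 0.23, 0.16 and 0.77 with doxycycline. With all 9 arrays none of the 3 was called with doxycycline (adjusted p = 0.251, 0.283 and 0.455). The other 5 fits gave 0 genes. MACC1 was the 1 gene called in both with the same sign: progestin raised it by 0.62 (SE 0.14, adjusted p = 0.0121) and doxycycline raised it further. Independent lists of these sizes would give 0.581 of each kind. Both comparisons contain the same progestin arrays with opposite sign, so chance alone makes their changes run against each other. The correlation across probe sets was -0.33 against -0.50 in simulated data without effects, and the covariance -0.0711 against -0.0454. Effects of progestin widen the spread of its changes and so weaken this correlation. The simulation leaves them out, so -0.50 is not the chance level here, nor in the brighter probe sets below. In the brighter 10607 probe sets the correlation was 0.0058 against -0.50, and the covariance 0.000528 against -0.00511, so that the difference from the simulation was -0.0258 over all probe sets and 0.00563 in the brighter ones. With changes computed from different progestin arrays the correlation was 0.0044 and the covariance 0.000274, and 0.0467 and 0.0049 in the brighter probe sets. Of the probe sets called for progestin 55.7% had an opposite sign with doxycycline, and 53.65% in the brighter ones. These calls came from all 3 progestin arrays, which favours opposite signs, so this share is not free of shared arrays.

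The count of probe sets moved back was 401, beside 280 with the same sign, with the F test first, where independent lists would give 141 and 129. In that setting neither comparison is held to its own adjusted p, so 401 stands at another threshold than the 1 reported. The count was 197, beside 150 with the same sign, with a variance trend and robust estimation (91.3 and 82.5 for independent lists). It was 66 beside 42 without the dimmest 25% of probe sets (34.2 and 30.7). Simulated data without effects gave 0 of either kind in each of these 3 settings. Independent lists leave out the shared progestin arrays, which favour opposite signs, and the simulation leaves out the effects, so neither gives the chance level of these counts. Most probe sets moved back were lower with progestin and higher with doxycycline: 327 against 74, 179 against 18 and 57 against 9, in the same order. Most calls with doxycycline were of higher values in these settings (874 of 1067, 478 of 530 and 140 of 158), which is also the sign of the change in 45 of the 48 long-mRNA genes. In all, 62 probe sets lay at least 2 lower on the log2 scale with progestin than with vehicle and at least 2 higher again with doxycycline. For 49 of them the lowest progestin value was on replicate 3, by a median of 10.4 below the next array, and 0 probe sets moved in the opposite pattern by as much.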

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

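Probe sets without a gene name in the annotation used here were outside the comparisons above. When every row of the table was tested, 1052 of these 12083 probe sets (8.71%) changed with progestin against vehicle, 446 higher and 606 lower. With progestin plus doxycycline against vehicle 876 changed, 508 higher and 368 lower. With doxycycline added to progestin 8 changed, 5 higher and 3 lower. What these probe sets measure was not examined here.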

How the results depend on the processing

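The scale with 16 added to the linear values, the F test first for counts of changed genes and the use of different vehicle arrays were chosen after the data were seen, and the other alternatives were planned. Progestin against vehicle gave 9502 probe sets with array weights, 3772 at an adjusted p of 0.01 and 2795 with a change of at least 1.5-fold, beside 6161. Leaving out 1 array gave 4632 to 6118. Progestin plus doxycycline against vehicle gave 3901 at an adjusted p of 0.01 and 2851 with at least 1.5-fold, beside 5953, and 4815 to 5889 with 1 array left out. Stricter thresholds lower a count by construction, and the cause of the other shifts was not tested. With doxycycline added to progestin, the 4 calls became 158 probe sets without the dimmest 25% of probe sets, a setting in which MACC1 was not tested. They became 12 with every row tested, 530 with a variance trend and robust estimation, 8 with array weights, 15 with 16 added to the linear values and 1067 with the F test first. The count was 0 with only the 2 groups fitted, 0 at an adjusted p of 0.01, and 0 to 2 with 1 array left out. Probe sets moved back, 1 as reported beside 1 with the same sign, numbered 2 with quantile normalization (beside 2 with the same sign) and 2 with median centring (beside 3). They numbered 66 without the dimmest 25% of probe sets (beside 42), 6 with every row tested (beside 1) and 197 with a variance trend and robust estimation (beside 150). There were 3 with array weights (beside 4), 3 with 16 added (beside 8) and 401 with the F test first (beside 280). The count was 0 at an adjusted p of 0.01 and 0 to 1 with 1 array left out. That 1 gene was ELF5 in 1 of the 9 fits, another gene in 3, and there was none in 5. The fit of only 2 groups and the fits without 1 array rest on fewer arrays. Changes from different progestin arrays gave a covariance of 0.000274 and a correlation of 0.0044. For the changes against vehicle with and without doxycycline, different vehicle arrays gave a covariance of 0.304 and a correlation of 0.703.

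The replicate numbers did not pair the arrays throughout: the deviations of same-numbered arrays correlated above 0.1 in 3 of 9 pairs (from -0.262 to 0.48), and 4 of the 9 arrays correlated best with their own number. Vehicle replicates 2 and 3 correlated at 0.48 and 0.464 with the same-numbered doxycycline arrays, and differently numbered pairs at most at 0.284. Same-numbered progestin and doxycycline arrays were at -0.141, -0.262 and -0.217. Pairing of some arrays is thus not settled. With a replicate block, progestin against vehicle gave 5378 probe sets, progestin plus doxycycline against vehicle 5240, progestin plus doxycycline against progestin 0, and 0 were moved back. The cause was not tested.

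With an estimated correlation 0 lists were called in progestin against vehicle, 0 in progestin plus doxycycline against progestin and 0 in progestin plus doxycycline against vehicle. Fry called 0 in the second and 17 in the third. Lists that changed direction were past the threshold in neither setting. With doxycycline added to progestin, the direction turned with fry for CDK inhibitors (adjusted p = 0.818), EGFR family (0.917), estrogen receptor and luminal (0.769), mitochondrial (0.971) and Wnt and Notch lists (0.917). It turned with quantile normalization for the cytosolic ribosome (0.113), hypoxia and glycolysis (0.875), p53 (0.993) and progestin-induced lists (0.875), and without the dimmest 25% of probe sets for the basal, cytosolic ribosome, ETS and progestin-induced lists (0.996 for each). With 1 array left out, it turned in at least 1 case for the basal (adjusted p from 0.816 to 0.99), CDK inhibitor (0.816 to 0.94), cytosolic ribosome (0.467 to 0.967), estrogen receptor (0.816 to 0.978), ETS (0.816 to 0.94), mitochondrial (0.255 to 0.925), p53 (0.816 to 0.989), progestin-induced (0.803 to 0.978) and Wnt and Notch lists (0.467 to 0.989). In progestin against vehicle this happened for the ATF4 (0.309 to 0.954) and stromal lists (0.209 to 0.9995). In progestin plus doxycycline against vehicle it happened for the ATF4 (0.554 to 0.984), stromal (0.233 to 0.923) and integrin lists (0.544 to 0.979), and the integrin list also turned with fry (0.464), quantile normalization (0.952) and without the dimmest 25% of probe sets (0.818). The cause was not tested.

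Of the values of single named genes under an alternative, 2534 kept their direction and side of the threshold, 107 lost the call, 23 gained it and 0 changed direction. These cover each gene in the comparison that named it, a limit set after the data were seen; in the comparison that had not named them, 88 values of named genes changed sign with doxycycline added to progestin and 4 in progestin against vehicle. For gene lists these numbers were 941, 50, 25 and 40. The lost calls of doxycycline added to progestin were those of ELF5, MACC1, ST6GAL1 and TMEM44, with an adjusted p of ELF5 from 4.25e-08 to 0.203 over all its alternatives. Dim probe sets are limited by values below 0 on the log2 scale, which carry no reliable order. The prior degrees of freedom of the variance model were 2.18 as deposited and 4.87 with 16 added, and the cause of that difference was not tested.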

Other observations

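The test of other cell types for the interferon genes and the regroupings that keep the vehicle arrays together were chosen after the result was seen. Interferon genes themselves were not described above, and those named here were chosen after their values were seen. Of 13 measured by a single-symbol probe set, 0 were called higher with progestin, with IFNB1 at a log2 change of 1.34 (95% interval -0.12 to 2.80, adjusted p = 0.161), IFNL2 at 0.78 (-0.07 to 1.62) and IFNL1 at 0.15 (-0.29 to 0.60).

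The interferon response list had mean levels of 5.99 to 6.38 on the vehicle arrays, 9.69 to 9.72 with progestin and 9.84 to 9.93 with progestin plus doxycycline. Neither vehicle nor progestin arrays had doxycycline by the labels, so induction of the hairpin does not enter the median change of 3.67 between them, and the median change with doxycycline added was 0.19. A broad rise of stromal, endothelial or immune cells in the cultures is argued against: the third quartile of the changes of their 20 markers was 0.26. A few such cells would not move that quartile, so the values do not exclude them. The most abundant markers lay at 9.08 and 9.38 (CDH5) and 8.60 and 8.17 (COL1A1) with vehicle and progestin, 3 of the 20 lay above the median of all genes, and 0 are in another list. Higher mRNA of an interferon gene stays open, with 0 of 13 called but an interval for IFNB1 that reaches 2.80, as does a response to the hormone. The IFNB1 probe set was dim, with a mean of 2.96 over all arrays, where the array medians of named probe sets were 7.19 to 7.28.

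Genes with long mRNAs had higher values with doxycycline as a list, while 0 of the 48 passed the test of single genes. The bounds for the tests of this pattern were set before their results were seen, on genes other than those in which it was noticed; 1 of the 114 genes listed, COL6A3, is also among the markers of stromal, endothelial and immune cells. The median change of 48 such genes lay at percentile 100 of 10000 random lists of the same size and mean expression (camera p = 7.06e-30, and p = 0.0385 with an estimated correlation), against percentile 17.3 for progestin against vehicle. RNA integrity or labelling that depends on transcript length is therefore a candidate explanation for part of the higher values with doxycycline. The largest range of the list median within a group was 0.517 of the difference between the groups, just above the bound set for it, so variation between single arrays cannot be told apart from it with 3 arrays per group. As deviations from each gene's mean, the list medians were 0.129, 0.325 and 0.284 on the doxycycline arrays. They were -0.0742, -0.216 and -0.111 on the progestin arrays, so these groups did not overlap. An effect of doxycycline or the hairpin on long transcripts was not tested and stays open, and mRNA lengths were not used here.

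With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Progestin against vehicle called 6161 probe sets and the highest other split 0 (1 of 10 splits as large, the real one included). Progestin plus doxycycline against progestin called 4 and the highest other 1 (1 of 10), and progestin plus doxycycline against vehicle 5953 and the highest other 0 (1 of 10). For gene lists the real split called 10 and the highest other 12 (3 of 10 as large), 5 and 5 (2 of 10), and 9 and 12 (3 of 10), in the same order. Every other split puts arrays of both groups into each fitted group. Where the groups differ, this widens the residuals and lowers the number of probe sets called, while part of the difference stays between the fitted groups. The other splits therefore give no chance level for probe sets or lists. With the vehicle arrays kept together and the 6 treated arrays regrouped, 3 of the 20 splits, the real one included, gave at least the 1 gene moved back, and the highest other gave 3; 20 splits are too few for a share under 0.05. Of 100 regroupings of all 9 arrays 4 gave at least 1 gene, but this count tests nothing about doxycycline: 96 of them spread the vehicle arrays over several groups, which raised the median residual standard deviation from 0.151 to between 0.203 and 0.243 and so lowers the number of calls. The highest of them gave 4479, with the 3 vehicle arrays together as the group that both comparisons share, which reflects a structure of the samples.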
